A study of Mus musculus with 16 samples.

How the data were processed

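Total RNA from bilateral amygdala punches of 16 male mouse samples was, per the labels, purified with an RNeasy kit, amplified into biotin-labelled cRNA (MessageAmp, Ambion) and hybridized to 1 Illumina array per sample, in 4 groups of 4. The steps by which the authors turned scans into the deposited values are not given in the sources used here.

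The main values are the intensity values deposited by the authors in the value table, on a linear scale from 35.48 to 22797.86. All 16 columns share their lowest and highest value and have medians of 60.09 to 60.67, so the deposited intensity values were already quantile-normalized between arrays. They were converted to log2 here. The detection p-values (p_value) were deposited by the authors in a second table, per the file headers, and their steps fit ranks among 936 negative controls. The second table also holds signal columns of intensity deposited under the same sample names. Their rows were not in the order of the probe identifiers: the Spearman correlation of a signal column with its own detection p was 0.0249 to 0.0872, against -0.967 to -1 for the value table. Of the signal columns 4, with sample numbers 13 to 16, held the arrays numbered 1 to 4 in the value table, and 12 held arrays found in the signal columns alone. The row order was recovered through the 4 shared arrays, and the signal columns were used as an alternative.

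The plan called for background correction with neqc (offset 16) of unnormalized signal. Since the deposited values were already quantile-normalized, log2 of the deposited values became the main setting and neqc an alternative. Probes with a detection p under 0.05 on at least 4 of 16 arrays were tested, 25054 of 45281. Of all probes 34885 had 1 gene symbol, 18 several and 10378 none, and 20644 tested probes with 1 symbol stood for 12254 genes. Where a gene had several probes, the probe with the highest mean over 16 arrays stood for it.

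In R 4.3.3 with limma 3.58.1, a model with 4 group means was fitted to each probe with default empirical Bayes moderation. The 5 comparisons were the stress effect at 6 days, at 8 days and averaged, the difference between the days, and the 8-day minus 6-day difference of unstressed samples. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. The 30 gene lists were tested with camera (preset correlation 0.01), adjusted over the 30 lists within a comparison. Camera asks whether a list moved relative to other genes. A correlation estimated per list widens its error for genes that vary together, and no call over the 16 arrays held with it, while over the 12 arrays with many detected probes the striatal list in unstressed samples did. Fry, which asks whether a list moved at all, called 0 of the 30 lists in each comparison, with camera at 1, 0, 1, 0 and 3 in the order given above. Exact permutation tests used all 70 assignments of 4 against 4 (smallest two-sided p 0.0286), or all 4900 within days for the average. The correlation of the stress effects of the days was set against 100 seeded reassignments within days (smallest p 0.0099). A list's score on an array is the mean, over its measured members, of the log2 value minus the gene's mean over 16 arrays.

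Comparisons, tests, gene lists, 14 fixed genes, the rule for naming genes and most alternatives were set before the data were examined. By that rule, with no gene passing, the 20 genes with the smallest unadjusted p were eligible for the stress effects and 10 for the other comparisons, with up to 4 members of a called list and 2 of other lists for the average effect. The limit of 20000 detected probes, the fit without the 4 arrays below it, the detected-probe covariate, neqc with offset 16 as an alternative and the use of the signal columns were chosen after the values were seen. Other alternatives were neqc with offset 50, median scaling, cyclic loess, normalization within days, 2 other filters, eBayes with trend and robust, array weights, a striatal score covariate, fits of 1 day, leaving out each array, and the mean over a gene's probes. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

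The arrays have no read depth, and their number limits the precision. The median standard error was 0.351 log2 units for a stress effect of 1 day and 0.248 for the average, and 0.218 and 0.154 over the 12 arrays. The fit was tested on simulated data with the measured noise of each array, or, over the 12 arrays, with 1 noise level per probe. Of 50 planted changes of each size, 8% were called for the average effect at a log2 change of 0.5, 36% at 1 and 94% at 2, and 0%, 10% and 76% at 6 days, while 5.13% to 5.59% of unchanged probes had an unadjusted p under 0.05 over the settings tested. A planted striatal list change of -0.5 gave a camera adjusted p of 0.000696, with 0 other lists called. The simulated genes varied independently, whereas the real striatal markers varied together within groups (mean correlation 0.251 over the 12 arrays). The planted list therefore does not show how often camera errs on genes that vary together. For the same reason the 5.13% to 5.59% do not show how the fit behaves where probes vary together. Random groupings of the real arrays within days gave up to 4444 of 25054 probes under 0.05 for the average effect.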

Results

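Gene expression was measured in the amygdala of male mice that had been immobilized once for 2 h, an acute psychological stressor, and of unstressed male mice. Tissue was taken 6 or 8 days later, with no further stressor, so the arrays describe a delayed state and not the immediate response. Each of the 4 groups (stressed and unstressed, at 6 and at 8 days) held 4 samples, each a bilateral punch of 1 mm diameter from 10 week old animals, hybridized to 1 Illumina array. The title of the series names Ppm1f, a phosphatase that removes activating phosphates from CaM kinase II, as a stress-regulated gene, so this gene was examined first. The labels number the samples but do not state that each came from its own animal, so the p-values measure only the spread between these samples.

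The arrays differed in how much RNA signal they recorded. Of 45281 probes, 21226 to 23164 were detected above background on 12 arrays, but 6868 and 17210 on stressed 6-day replicates 1 and 2, and 13893 and 11852 on unstressed 8-day replicates 3 and 4. The median correlation of these 4 arrays with the others was 0.521, 0.832, 0.726 and 0.657, against 0.927 to 0.96 for the other 12. The low arrays sat in opposite arms of the stress comparison on the 2 days, and values over the 12 arrays with many detected probes, a choice made after the data were seen, are therefore given beside those that shrank or turned most without the 4. Sample numbers also conflicted: the 4 arrays that stand as stressed 6-day samples in the table used here are stored under the numbers of the unstressed 8-day samples in the other deposited table. The deposited detection p-values follow the numbering used here, so the groups were kept as the labels give them, and each group difference rests on that numbering.

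**Figure D1:**
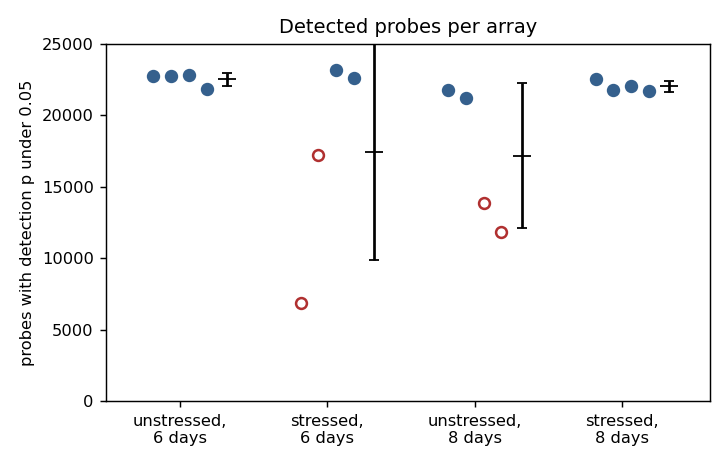
Number of probes with a detection p under 0.05 on each array (vertical axis) by group (horizontal axis), with open red symbols for the 4 arrays under 20000 and bars for the mean and SD of all 4 arrays of a group. The lowest array, in the stressed 6-day group, detected 6868 probes, and the unstressed 6-day and stressed 8-day groups held no array under 21724.

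Ppm1f was detected on all 16 arrays by its brightest probe (ILMN_1221199) and did not pass the test for stress on either day. Its mean log2 intensity was 8.60 ± 0.81 (SD, n = 4) in stressed and 7.87 ± 0.25 (SD, n = 4) in unstressed samples at 6 days, and 8.17 ± 0.41 (SD, n = 4) and 8.28 ± 1.09 (SD, n = 4) at 8 days. The stressed minus unstressed difference was 0.73 ± 0.47 (SE; exact permutation p = 0.0571, limma adjusted p = 0.678) at 6 days and -0.11 ± 0.47 (SE; exact permutation p = 0.886, adjusted p = 0.945) at 8 days, and averaged 0.31 ± 0.33 (SE; exact permutation p = 0.409, adjusted p = 0.998). The highest values, 9.80, 9.32 and 9.10, came from the 3 arrays with the fewest detected probes, of which 1 was stressed and 2 were unstressed. Over the 12 other arrays Ppm1f was higher with stress by 0.28 ± 0.25 (SE) at 6 days, with 2 stressed and 4 unstressed arrays (exact permutation p = 0.267, limma adjusted p = 0.927). At 8 days it was higher by 0.83 ± 0.25 (SE), with 4 stressed and 2 unstressed arrays (exact permutation p = 0.133, limma adjusted p = 0.7). With 4 against 2 arrays, an exact permutation p of a single day cannot fall under 0.05. The average over these 12 arrays was 0.55 ± 0.18 (SE; two-sided exact permutation p = 0.0222), with an adjusted p of 0.562 over all probes. A dimmer Ppm1f probe (ILMN_2792756), close to background, gave -0.07 at 6 and 0.07 at 8 days (SE 0.205 for each), and the remaining probe was below the detection filter. Over the 12 arrays the dimmer probe averaged 0.005 ± 0.108 (SE; exact permutation p = 0.969), so only the brightest probe showed the rise there. The signal columns of the other deposited table turned the direction, with -0.13 at 6 days (exact permutation p = 0.771) and -0.34 for the average. The unstressed 8-day arrays behind that average are the 4 that stand as stressed 6-day samples here, so it is no independent test. The groups behind the 6-day value of the signal columns follow the same conflicting numbering and are uncertain.

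**Figure D2:**
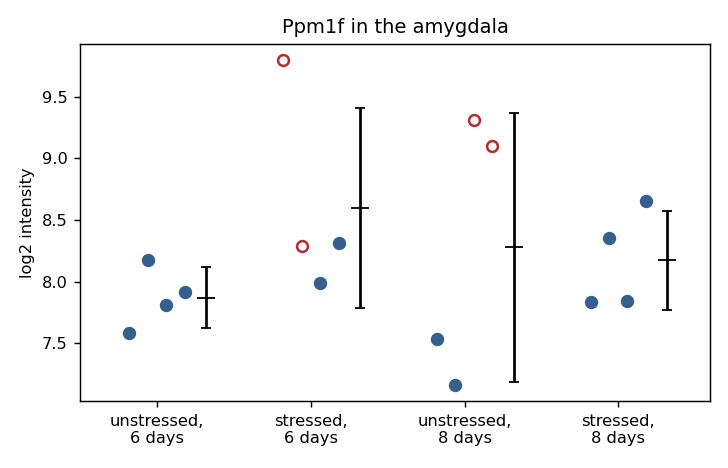
Log2 intensity of the brightest Ppm1f probe on each array (vertical axis) by group (horizontal axis), with open red symbols for the 4 arrays with few detected probes and bars for the mean and SD of all 4 arrays of a group. The highest symbols, at 9.80, 9.32 and 9.10, are all open, and the filled symbols lie between 7.16 and 8.66.

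At 6 days after immobilization, markers of striatal projection neurons were lower as a group in stressed than in unstressed samples, while no single probe passed the test. Of 17 measured striatal markers 13 were lower, with a median log2 difference of -0.58 (camera adjusted p = 0.0104; adjusted p = 0.92 with an estimated correlation, where the call was lost). None of the 17 passed singly over all probes, nor with p-values adjusted over the list alone. Over the 12 arrays the median shrank to -0.30, with 16 of 17 lower (adjusted p = 0.000351; adjusted p = 0.791 with an estimated correlation). Scn4b, a sodium channel beta subunit abundant in striatal neurons, gave -1.48 ± 0.52 (SE, n = 4). The dopamine receptors Drd1 and Drd2 gave -1.22 ± 0.53 (SE) and -0.63 ± 0.25 (SE), and the synaptic protein gene Syndig1l gave -1.46 ± 0.62 (SE). Each had an adjusted p of 0.678. These 4 genes gave -0.72, -0.29, -0.42 and -0.62 over the 12 arrays, and the other probe of Syndig1l had the opposite sign (0.24). The mean striatal marker score was -0.08 ± 0.35 (SD, n = 4) in stressed and 0.52 ± 0.30 (SD, n = 4) in unstressed samples, and each of the 4 unstressed samples lay above each stressed sample (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows, and 0.286 after adjustment over 30 lists). Scores of pan-neuronal markers and of basolateral amygdala and cortical excitatory markers were separated in the same way at 6 days, each lower with stress and with the same exact permutation p of 0.0286 (0.286 after adjustment). The unstressed 6-day group had the highest mean striatal score of the 4 groups. Unstressed 8-day samples averaged -0.06 ± 0.57 (SD, n = 4) and stressed 8-day samples -0.38 ± 0.08 (SD, n = 4). The striatal score differed by -0.60 with stress at 6 days, and by -0.58 between unstressed 8-day and 6-day samples. The latter had a two-sided exact permutation p of 0.143 (0.429 after adjustment over 30 lists).

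**Figure D3:**
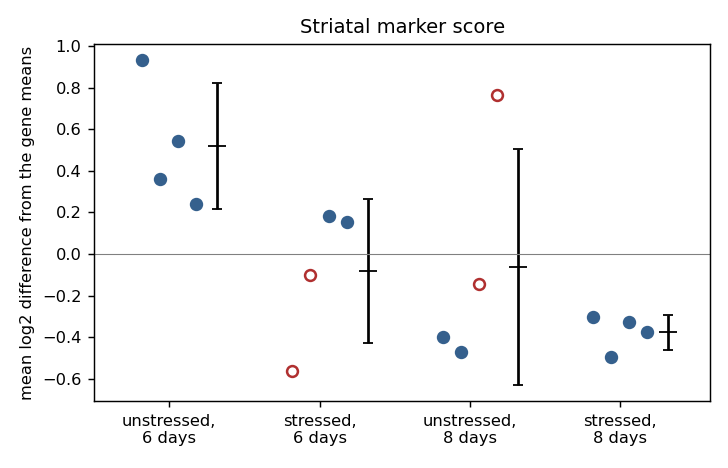
Striatal marker score of each array, the mean log2 difference of 17 striatal genes from their means over 16 arrays (vertical axis), by group (horizontal axis), with open red symbols for the 4 arrays with few detected probes and bars for the mean and SD of all 4 arrays of a group. Unstressed 6-day samples averaged 0.52 and stressed 8-day samples -0.38.

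The 20 genes with the smallest unadjusted p at 6 days all had an adjusted p of 0.678. Vit, an extracellular matrix protein, gave 0.99 ± 0.20 (SE) and the homeobox gene Rhox5 1.39 ± 0.30 (SE). Rpap1, an RNA polymerase II associated protein, gave 1.48 ± 0.34 (SE), and Ikbkb, a kinase that activates NF-kappaB, 0.84 ± 0.22 (SE). Lower values were found for the zinc finger genes Zfp300, at -1.72 ± 0.39 (SE), and Zkscan5, at -1.33 ± 0.32 (SE). Plcb1, a phospholipase C that couples receptors to calcium release, gave -0.83 ± 0.20 (SE). Vit was detected on 0 and Rhox5 on 1 of 4 unstressed 6-day arrays, and Zfp300 and Plcb1 on 1 of 4 stressed ones, so the size of these differences depends on the background level. Arpp21, a cAMP-regulated phosphoprotein abundant in striatum, gave -1.55 ± 0.42 (SE), the calmodulin-dependent phosphodiesterase Pde1c -1.35 ± 0.38 (SE) and the dehydrogenase Dhrs7 -1.11 ± 0.28 (SE). Without the 4 low arrays Rpap1 gave 0.94, Ikbkb 0.56, Arpp21 -0.79, Pde1c -0.80 and Dhrs7 -0.63. Other probes of Arpp21 did not point one way, with 4 of 7 of opposite sign, nor did those of Ikbkb (1 of 1) and Pde1c (1 of 3). Among stress-system genes, Fkbp5, a glucocorticoid-induced co-chaperone of the glucocorticoid receptor, gave -0.94 over all arrays and 0.14 over the 12, and Crh, the corticotropin-releasing hormone, -0.63 and -0.23. The glucocorticoid-induced kinase Sgk1 gave -0.67 and -0.33, the glucocorticoid receptor Nr3c1 -0.24 and -0.07, and the receptor of the peptide PACAP, Adcyap1r1, -0.59 and -0.09. Of 22 measured glucocorticoid receptor targets 15 were lower and none passed the test (median -0.25, list adjusted p = 0.881). Without the low arrays 14 of 22 were higher (median 0.08, adjusted p = 0.641). Pan-neuronal markers were lower in 16 of 19 genes (median -0.45, list adjusted p = 0.054), and over the 12 arrays their median was -0.06 (adjusted p = 0.486). Over those 12 arrays 3 lists passed: the striatal markers, and, higher with stress, ribosomal proteins (adjusted p = 5.59e-05) and astrocyte markers (adjusted p = 0.0015), at 0.791 for each of the 3 with an estimated correlation. In all, limma called 0 of 25054 probes, while 1447 had an unadjusted p under 0.05, against 1253 for uniform p-values. Splits of the same arrays gave 406 to 586 where the low arrays were parted and 924 to 1447 where they shared an arm. The striatal call was lost without stressed replicate 3 or 4 or unstressed replicate 1 (adjusted p = 0.0679, 0.0617 and 0.107). The difference of the striatal score was -0.60 with all arrays, -0.69 and -0.68 without either stressed replicate, and -0.46 without the unstressed one.

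At 8 days after immobilization no gene list and no single probe passed the test, and the genes with the smallest p were mostly higher in stressed samples. The differences of the 20 genes with the smallest p were all smaller over the 12 arrays. Gfap, the intermediate filament of astrocytes, showed a large difference of 2.43 ± 0.63 (SE, n = 4; limma adjusted p = 0.66), and 1.44 over the 12 arrays. It was called with p-values adjusted over the list alone among the 19 astrocyte markers, of which 14 were higher (list adjusted p = 0.415), but not over the 12 arrays. In the inflammation and interferon list 2 of 19 genes were higher with p-values adjusted over the list alone, against 0 over all probes (list adjusted p = 0.439) and 0 over the 12 arrays. The 4 genes of that list with the smallest p were Gfap, Ifitm3, an interferon-induced membrane protein, at 1.41, the immunoproteasome subunit gene Psmb8, at -0.57, and the class I histocompatibility gene H2-D1, at 0.99. The last 3 gave 0.69, -0.30 and 0.55 over the 12 arrays. Dab1, the adaptor of reelin signalling, gave 1.52 ± 0.38 (SE) and the acid-sensing channel Asic2 1.34 ± 0.35 (SE). The growth cone protein gene Dpysl3 gave 1.02 ± 0.26 (SE) and Miga2, a regulator of mitochondrial fusion, 1.65 ± 0.37 (SE). Socs4, a suppressor of cytokine signalling, gave 1.06 ± 0.26 (SE), the orphan receptor Gpr173 1.66 ± 0.44 (SE) and Gli2, a transcription factor of hedgehog signalling, 0.96 ± 0.27 (SE). The actin-binding protein gene Cttn was at -0.99 ± 0.27 (SE). Of the 4 unstressed 8-day arrays, Gli2 was detected on 0, Socs4 on 1, and Miga2, Dab1, Asic2 and Gpr173 on 2 each, so the size of these differences depends on the background level. The last 4 genes gave 0.94, 0.64, 0.62 and 0.97 over the 12 arrays, with Cttn at -0.54. Other probes of opposite sign were 1 of 1 for Socs4 and for Camk2a, and 1 of 3 for Cttn. Camk2a, the alpha subunit of CaM kinase II, gave 0.84 over all arrays and -1.05 over the 12, and Camk2b gave 0.50 and 0.19. The 17 striatal markers had a median of -0.03 (list adjusted p = 0.418) and of 0.13 over the 12 arrays. Blood cell markers were higher in 5 of 5 genes (median 0.89, list adjusted p = 0.209). In the 12 arrays this was 4 of 5 (median 0.35, adjusted p = 0.142). Hypothalamic and thalamic markers passed as a list over the 12 arrays, higher with stress (median 0.30, adjusted p = 0.0403; adjusted p = 0.748 with an estimated correlation). In all, limma called 0 of 25054 probes, while 1639 had an unadjusted p under 0.05.

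Averaged over both days, striatal markers were lower as a group after stress, with 15 of 17 genes lower and a median of -0.35 (camera adjusted p = 6.7e-05; adjusted p = 0.811 with an estimated correlation, where the call was lost). It was also lost over the 12 arrays (camera adjusted p = 0.153, median -0.13) and with fry (adjusted p = 0.877). Unstressed 8-day replicate 4, a low array, had a striatal score of 0.77, against -0.40, -0.47 and -0.15 on replicates 1, 2 and 3 of its group. Without it the camera adjusted p rose to 0.0382. Drd1, the D1 dopamine receptor, had the smallest p of the list at -1.33 ± 0.37 (SE; limma adjusted p = 0.998) and was the 1 member called with p-values adjusted over the list alone. Its difference was -0.44 over the 12 arrays, where 0 members were so called. Ido1, a tryptophan-degrading enzyme, gave -0.49 ± 0.21 (SE), Syndig1l -1.01 ± 0.44 (SE) and Ppp1r1b, the dopamine-regulated phosphatase inhibitor DARPP-32, -0.70 ± 0.34 (SE), against -0.21, -0.32 and -0.20 over the 12 arrays. The other probe of Syndig1l again had the opposite sign (0.04).

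No other list passed for the average effect, and the following members are given as values. Among GABA genes, 8 of 17 higher, the astrocytic GABA transporter Slc6a11 gave 0.57 ± 0.21 (SE) and the receptor subunit Gabrg1 0.57 ± 0.24 (SE), with 0.31 for Gabrg1 over the 12 arrays. Among stress peptide genes, 20 of 40 higher, the neuropeptide Vip gave -0.88 ± 0.30 (SE) and the cannabinoid receptor Cnr1 -0.44 ± 0.20 (SE), with -0.36 for Vip and -0.61 for Cnr1 over the 12 arrays. The corticotropin-releasing hormone receptor Crhr1 gave -0.12, or -0.19 over the 12 arrays, and the nociceptin receptor Oprl1 0.78, or 0.22. The neurokinin B gene Tac2 and its receptor Tacr3 gave 0.28 and -0.07, against 0.58 and 0.59 over the 12 arrays. Astrocyte markers were higher in 13 of 19 genes (list adjusted p = 0.236), with Agt, the angiotensinogen gene, at 0.38 ± 0.16 (SE) and the transcription factor Sox9 at -0.48 ± 0.21 (SE). In the excitatory list of basolateral amygdala and cortex, Neurod1 gave 1.07 ± 0.38 (SE), or 0.70 over the 12 arrays, and Rspo2, which marks a class of basolateral neurons, -0.41 ± 0.26 (SE). The neuronal cytoskeleton genes Ina and Tubb3 gave -0.46 ± 0.18 (SE) and -0.34 ± 0.18 (SE), and the chaperone Hsp90aa1 -0.30 ± 0.13 (SE). The growth factor Bdnf gave 0.33 and the activity-induced gene Fos 0.26. The 3 other Bdnf probes all had the opposite sign. Bdnf and Fos turned to -0.18 and -0.05 over the 12 arrays. Bdnf was far above the rest of its group, at a log2 value of 9.59, on stressed 6-day replicate 1. Among single genes with the smallest p, Sytl4, a granule exocytosis protein, gave 1.61 ± 0.32 (SE), Insyn2b, related to a protein of inhibitory synapses, 0.94 ± 0.20 (SE), and Socs4 0.86 ± 0.18 (SE). Pank3, an enzyme of coenzyme A synthesis, gave 0.81 ± 0.20 (SE) and Sfrp2, a secreted Wnt modulator, 0.74 ± 0.20 (SE). Arrb2, a beta-arrestin, gave 1.11 ± 0.32 (SE), and the transcription factor Rfx4 -0.83 ± 0.20 (SE), with 0.55 for Arrb2 and -0.51 for Rfx4 over the 12 arrays. Agt was detected on 0 of 4 arrays of each unstressed group, Ido1 and Crhr1 on 0 of 4 stressed 8-day arrays, and Insyn2b and Socs4 on 1 of 4 unstressed 8-day arrays, so they lay close to background there. Other probes of opposite sign were 1 of 1 for Socs4, Tacr3 and Rspo2 and 1 of 2 for Rfx4. Of all these genes Tacr3 had an adjusted p of 0.999 and the others 0.998. For the average effect limma called 0 of 25054 probes, while 990 had an unadjusted p under 0.05, against 1253 for uniform p-values. In 26 of 100 groupings of the arrays within days, the real one included, the count was at least 990. Over the 12 arrays, 1907 probes had an unadjusted p under 0.05. There astrocyte (adjusted p = 0.00133) and oligodendrocyte markers (adjusted p = 0.031) passed as higher and the basolateral and cortical excitatory markers as lower (adjusted p = 0.0365), each at 0.798 with an estimated correlation.

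The stress effects at 6 and 8 days were compared directly to ask whether the delayed state changed between the days. No probe and no list passed the test of the difference. Among the genes with the smallest p, not all of which are given, the 8-day minus 6-day effect was 2.79 ± 0.55 (SE, n = 4) for Zfp300, 2.53 ± 0.62 (SE) for Gpr173, 2.01 ± 0.49 (SE) for the membrane protein gene Ckap4, 1.88 ± 0.48 (SE) for the transcriptional corepressor Rcor1 and -1.68 ± 0.42 (SE) for Rhox5 (limma adjusted p = 0.444 for each). Gpr173 gave 1.56, Ckap4 1.19 and Rcor1 0.81 over the 12 arrays. Of 25054 probes limma called 0, and 2574 had an unadjusted p under 0.05. Across the same probes, which are not independent of each other, the fold changes of the 2 days were correlated at r = -0.379 (Spearman rho = -0.364). This was no farther from 0 than in 16 of 100 random reassignments of the arrays within days (permutation p = 0.168), and over the 12 arrays r was 0.143 and rho 0.116 (permutation p = 0.0297 and 0.0792). Over those 12 arrays, ribosomal proteins and striatal markers differed between the days (adjusted p = 0.000428 and 0.0019; 0.866 for both with an estimated correlation), with 8-day minus 6-day medians of -0.21 and 0.46.

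Between the unstressed groups, which serve as the background level of variation between days, striatal, oligodendrocyte and blood cell markers fell as groups from the 6-day to the 8-day samples. Striatal markers were lower in 14 of 17 genes (median -0.65, camera adjusted p = 0.00164; adjusted p = 0.806 with an estimated correlation), of which 2 were called with p-values adjusted over the list alone, and 12 over the 12 arrays. Oligodendrocyte and myelin markers were lower in 15 of 18 (median -0.53, adjusted p = 0.0198) and blood cell markers in 5 of 5 (median -1.05, adjusted p = 0.0198), of which 0 and 3 were called with p-values adjusted over the list alone, and 5 and 0 over the 12 arrays. With an estimated correlation the adjusted p was 0.806 for these lists as well. Without the 4 low arrays the myelin list had a median of -0.47 (adjusted p = 1.35e-10; adjusted p = 0.237 with an estimated correlation) and the blood cell list of -0.47 (0.0126; adjusted p = 0.369 with an estimated correlation). Scn4b gave -2.45 ± 0.52 (SE, n = 4; limma adjusted p = 0.611), the phosphodiesterase Pde1b -0.77 ± 0.22 (SE), the striatal receptor gene Gpr6 -0.63 ± 0.23 (SE) and Drd2 -0.65 ± 0.25 (SE). Gpr6 was detected on 0 of 4 unstressed 8-day arrays, so its difference was taken against background. In the myelin list, the lineage transcription factor Sox10 gave -0.91 ± 0.27 (SE), the myelin enzyme Cnp -1.41 ± 0.46 (SE), transferrin (Trf) -1.25 ± 0.44 (SE) and the tight junction protein Cldn11 -0.79 ± 0.28 (SE). Cnp, Trf and Cldn11 gave -0.62, -0.55 and -0.50 over the 12 arrays, and Sox10 was detected on 1 of 4 unstressed 8-day arrays. The haemoglobin genes Hba-a1, Hbb-bs and Hbb-bt gave -1.32 ± 0.47 (SE), -1.05 ± 0.36 (SE) and -1.57 ± 0.64 (SE), and Hbb-b2 -0.31 ± 0.36 (SE), against -0.28, -0.52, -0.53 and -0.47 over the 12 arrays. The blood cell score was -0.94 and -1.34 on the 2 unstressed 8-day arrays with few detected probes and -0.06 and -0.11 on the others of that group. Sequence shared between globin genes leaves their separate values uncertain. Outside the lists, the transporter gene Slc35d3 gave -1.47 ± 0.35 (SE), Dab1 -1.45 ± 0.38 (SE) and protein kinase D3 (Prkd3) -1.06 ± 0.27 (SE), with -0.57 for Dab1 and -0.68 for Prkd3 over the 12 arrays. In all, limma called 0 of 25054 probes, and 1789 had an unadjusted p under 0.05. Over the 12 arrays limma called 1 probe, that of Scn4b (-2.68 ± 0.28 SE, adjusted p = 0.0157), whose other probe had the opposite sign over all arrays (0.46), and the striatal list was at a median of -0.96 (adjusted p = 0.0425 with an estimated correlation). Without unstressed 8-day replicate 1 or 2, the adjusted p of the striatal list over the remaining arrays was 0.168 and 0.182, with a score difference of -0.47 and -0.45 against -0.58 with all arrays. The myelin and blood cell lists were also lost there (adjusted p = 0.168 and 0.0813 without replicate 1, 0.182 and 0.156 without replicate 2) and without unstressed 6-day replicate 3 (0.0546 and 0.0579). In these 3 fits the myelin score differed by -0.54, -0.50 and -0.47, against -0.50 with all arrays, and the blood cell score by -1.07, -1.05 and -0.82, against -0.89. The myelin list was lost with a stricter detection filter (adjusted p = 0.0597), and the blood cell list with median scaling (0.058) and with no filter (0.051). Neither was called in the signal columns of the other table (adjusted p = 0.99 and 0.594). There the unstressed 8-day columns hold the arrays that stand as stressed 6-day samples here.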

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

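The tests on the arrays with few detected probes, on the difference of lists between days over 12 arrays, on Ppm1f and on the striatal score as a response to stress were chosen after the results were seen, while the counts over other splits of the samples and the covariation of striatal markers were planned.

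An array was set apart where its gap to the nearest array of its group, divided by the range of the group, exceeded the 95% critical value of Dixon's test. This was so in 28 of 412 groups of values tested, and chance gives about 1 in 20; 17 of the 28 were on the 4 arrays with few detected probes and 11 on others. Unstressed 6-day replicate 4 had 21876 detected probes. On stressed 6-day replicate 1, scores stood apart for pan-neuronal (-1.36), cholesterol synthesis (-0.985), circadian clock (-0.87), monoamine (-0.608), microglia (-0.353) and Ppm1f and CaM kinase genes (-0.274), as did log2 values of Bdnf (9.59), Slc6a11 (5.77), Scn4b (5.68) and Syndig1l (5.59). On stressed 6-day replicate 2 these were Arrb2 (8.71) and Sgk1 (7.09). On unstressed 8-day replicate 4 they were the chromatin (-0.331) and glutamate receptor scores (-0.237) and Pde1b (8.06), and on replicate 3 Rpap1 (8.81) and Sfrp2 (7.84). On arrays with many detected probes they were the synaptic vesicle score (-0.01), Zfp300 (6.29) and Cttn (6.48) on stressed 8-day replicate 4, and the central amygdala score (-0.511) and Tac2 (6.31) on replicate 2. Nr3c1 (6.65) stood apart on stressed 8-day replicate 1, Hba-a1 (7.57) on replicate 3, Insyn2b (6.67) and Hbb-b2 (6.69) on unstressed 8-day replicate 1, and Pank3 (6.44) on unstressed 6-day replicate 3.

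Over the 12 arrays with many detected probes, the stress effect differed between days for ribosomal proteins (adjusted p = 0.000428) and striatal markers (adjusted p = 0.0019) in a camera test of the difference itself, and both calls were lost with an estimated correlation (adjusted p = 0.866 for each). The signal columns of the second table held 12 arrays that the comparisons of the report do not use.

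For the number of probes with an unadjusted p under 0.05 at 6 days, 1 of all 35 splits, the real one, reached 1447, and the highest other gave 1340. That share is under 0.05, but it is the smallest that 35 splits allow and was not adjusted for the other counts tested. Chance is therefore not excluded. The counts followed the 2 arrays with few detected probes: the 15 splits with both in 1 arm gave 924 to 1447 and the 20 that part them 406 to 586. The 15 are too few for a share under 0.05, so this count is no sign of an effect of stress. The signal columns gave 417 probes. Their unstressed 8-day columns hold the same 2 arrays with few detected probes, and all columns share 1 estimate of the spread. The 417 therefore cannot decide for or against an effect of stress. In the comparisons at 8 days and of unstressed samples the splits with both low arrays in 1 arm gave 1515 to 3099 and 1472 to 2026, and those that part them 486 to 800 and 302 to 446. Chance cannot be excluded for the other counts of such probes, too. At 8 days 11 of 35 splits reached the real 1639 (highest other 3099), for the average 26 of 100 reached 990 (4444), for the difference between days 10 of 100 reached 2574 (4420), and for unstressed samples 4 of 35 reached 1789 (2026). Splits with several times the real count for the average point to a structure of the samples. For gene lists, chance cannot be excluded either: 2 of 35 splits gave as many as the 1 at 6 days (highest other 2), 36 of 100 as many as the 1 for the average (6), and 4 of 35 as many as the 3 in unstressed samples (3).

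Stress effects at 6 and 8 days ran in opposite directions across probes (r = -0.379), though not beyond chance (permutation p = 0.168). Without the 4 arrays with few detected probes r was 0.143, so these arrays, in opposite arms on the 2 days, may account for the sign. With the number of detected probes as a covariate r was 0.246 and no longer negative. No reassignments were run for that fit, and over reassignments of all 16 arrays r had an SD of 0.229. The covariate also differed with stress, at a mean of 17457 against 22540 probes at 6 days and 22039 against 17190 at 8 days. This fit therefore cannot decide whether responses to stress were opposite on the 2 days.

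Striatal markers were lower in stressed than in unstressed samples at 6 days. Arrays with few detected probes stay open as a cause: without those 4 the camera adjusted p was 0.000351, but the median shrank from -0.58 to -0.30 and the call was lost with an estimated correlation (adjusted p = 0.791). Different shares of striatal tissue in the punches may contribute: the markers varied together within groups over the 12 arrays, with a mean correlation of 0.251 against a 95th percentile of 0.0678 in 1000 random lists. Ribosomal proteins (0.211) and immediate early genes (0.11) also lay above 0.0678, while pan-neuronal markers (0.0268) did not. Varying together more than random genes therefore does not single out tissue shares. A response to stress cannot be told apart from dissection, as both predict the separation seen at 6 days (exact permutation p = 0.0286). Some members of the list, Ppp1r1b, Tac1 and Penk among them, are also expressed in the amygdala.

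Ppm1f was highest on the arrays with few detected probes. Whether low array quality raised its value stays open, since over the 12 other arrays, which span a narrow range of detected probes, Ppm1f showed no relation to their number (r = 0.167, permutation p = 0.604, rho = -0.028). The 2 unstressed arrays with few detected probes exceeded the 6 stressed arrays with many by 1.04 (9.21 against 8.17 ± 0.33 SD). The pattern itself places these unstressed arrays among the highest, so this comparison cannot decide whether stress raised Ppm1f. Over the 12 other arrays a rise with stress stays open (two-sided exact permutation p = 0.0222), because the adjusted p over all probes was 0.562. The dimmer Ppm1f probe, close to background, did not show it (0.005 ± 0.108 SE, exact permutation p = 0.969). In the signal columns Ppm1f differed by -0.133 at 6 days (exact permutation p = 0.771) and by -0.336 for the average. That average counts as unstressed the 4 arrays that stand as stressed 6-day samples in the value table, so it is no independent test. The groups behind the 6-day value follow the same conflicting numbering and are uncertain.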

How the results depend on the processing

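The fits without the 4 arrays with under 20000 detected probes, with the number of detected probes as a covariate, with neqc offset 16 and on the signal columns, and the alternatives for each called list, were chosen after the results were seen. Values are log2 differences for Ppm1f, adjusted p for lists, r across probes for the 2 days, and counts of lists or probes called. The cause was not tested where a value moved.

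The number of lists called at 6 days was 2 with neqc offset 50, median scaling, cyclic loess, eBayes with trend and robust, the mean of a gene's probes (2 for the average) and the detected-probe covariate. Median scaling gave 0.203 for Ppm1f at 8 days and 0.058 for the blood cell list in unstressed samples. With no filter the lists called were 3 at 6 days, 1 at 8 days, 2 for the difference between days and 8 in unstressed samples, with 0.051 for the blood cell list. The strict filter gave 0.0597 for the oligodendrocyte list.

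Array weights gave 0.764 for Ppm1f at 8 days, r = 0.142, 2 probes called in unstressed samples (Scn4b and Ppp1r1b), and 4, 3, 4, 2 and 6 lists at 6 days, at 8 days, for the average, the difference and unstressed samples. Without the 4 arrays these were 0.826, r = 0.143, 1 probe, and 3, 1, 3, 2 and 5 lists, with 0.153 for the average striatal list. The detected-probe covariate gave 0.551, r = 0.246 and 2 lists for the difference.

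With the striatal score as a covariate 0 lists were called at 6 days, for the average and in unstressed samples, with the striatal list at 0.988, 0.975 and 0.952, the oligodendrocyte list at 0.629 and the blood cell list at 0.172. The score is the mean of the striatal genes themselves, so the loss of the striatal list was fixed beforehand and says nothing on its stability. With an estimated correlation 0, 0 and 0 lists were called, with the striatal list at 0.92, 0.811 and 0.806 and the oligodendrocyte and blood cell lists at 0.806. With fry 0, 0 and 0 were called, with 0.701, 0.877 and 0.302, and 0.302 and 0.186.

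The signal columns gave Ppm1f -0.133 at 6 days and -0.336 for the average, r = 0.000924, 2 lists at 6 days, 2 for the average and 1 for the difference, and 0.99 and 0.594 for the oligodendrocyte and blood cell lists. Their unstressed 8-day columns hold arrays that stand as stressed 6-day samples in the value table. Only their 6-day difference therefore rests wholly on other arrays, whose groups follow a numbering that conflicts with the one kept here.

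Leaving out each array in turn gave 0 probes called in the stress comparisons and 0 to 1 in unstressed samples (Scn4b without stressed 6-day replicate 1, adjusted p = 0.0253). Ppm1f ranged from 0.328 to 0.932 at 6 days, -0.479 to 0.24 at 8 days and 0.111 to 0.484 for the average, and r from -0.422 to -0.153. Lists called ranged from 0 to 2, 0 to 1, 1 to 4, 0 to 0 and 0 to 3. The striatal list ranged from 0.000399 to 0.107 at 6 days, 6.04e-06 to 0.0382 for the average and 1.12e-11 to 0.182 in unstressed samples, the oligodendrocyte list from 0.000429 to 0.182 and the blood cell list from 0.0097 to 0.156. The striatal call at 6 days was lost without stressed replicates 3 (0.0679) and 4 (0.0617), where the score difference grew from -0.601 to -0.689 and -0.68, and without unstressed replicate 1 (0.107), where it was -0.463.

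Of 217 values of named genes recomputed under 31 settings, 98 kept their sign throughout and 222 of 6332 recomputed values had the other sign, 97 of them on the signal columns. Over all settings the number of probes with an unadjusted p under 0.05 was 417 to 3384 at 6 days, 748 to 3820 at 8 days, 393 to 2040 for the average, 362 to 4570 for the difference and 703 to 4290 in unstressed samples. The authors' processed values and values with no background correction, listed as other settings in the plan, are the main values themselves. The slide was not given, so no fit with it as a block was run. No paired analysis was possible because the labels pair no samples. With 4 samples per group, small changes escape the test.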

Other observations

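The tests over the 12 arrays with many detected probes and those on the signal columns of the second table were chosen after the values were seen.

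In the signal columns, striatal markers were lower in 6-day samples named stressed than in those named unstressed. The value table does not hold these 8 arrays, and their names follow the numbering that conflicts with the one kept here. Their groups are therefore uncertain, and the difference is no independent test of stress. The mean striatal score was -0.43 ± 0.31 (SD, n = 4) in stressed and 0.40 ± 0.10 (SD, n = 4) in unstressed samples (two-sided exact permutation p = 0.0286, the smallest possible). The stressed samples had -0.64, -0.73, -0.27 and -0.08, and the unstressed samples 0.28, 0.36, 0.45 and 0.52. At 8 days the signal columns ran the other way, with 0.17 ± 0.29 (SD, n = 4) in stressed and -0.14 ± 0.35 (SD, n = 4) in unstressed samples (exact permutation p = 0.229), and the striatal difference between the days was called by camera (adjusted p = 1.28e-09). These unstressed 8-day columns are the 4 arrays that stand as stressed 6-day samples in the value table. At 6 days Ppm1f differed by -0.13 in the signal columns (exact permutation p = 0.771). The labels do not say whether these arrays came from the same tissue as those of the value table, and the best correlation of each with an array of that table was 0.897 to 0.985.

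Over the 12 arrays, the neurokinin B gene Tac2 averaged 0.58 ± 0.15 (SE) with stress and its receptor Tacr3 0.59 ± 0.21 (SE), with adjusted p of 0.495 and 0.571. Central amygdala markers were lower in unstressed 8-day than 6-day samples as a list over these arrays (adjusted p = 0.00283), and the basolateral and cortical excitatory markers were higher (adjusted p = 9.54e-05). Both calls were lost with an estimated correlation (adjusted p = 0.237 and 0.15). Within groups, the oligodendrocyte markers varied together most (mean correlation 0.46), followed by blood cell (0.393) and choroid plexus markers (0.266).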
